A study of Mus musculus with 14 samples.

How the data were processed

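Bone marrow of 14 B6 mice, 5 of them young and 9 of middle age, was profiled by droplet single-cell RNA sequencing of 3' ends. Per the labels' protocols, niche cells were digested and sorted and hematopoietic cells were sorted after a density gradient, and each mouse gave 1 library on its own lane. Reads were processed with bcl2fastq 2.20.0.422 and Cell Ranger 6.0.0 against mm10 (GRCm38), per the submitters' processing notes, and the version of Cell Ranger also stands in the file headers. The deposited values are raw UMI counts per gene and barcode, with 32285 genes and 106852 barcodes over the 14 libraries. The replicates were checked for being separate draws, and the lowest chi-squared per degree of freedom between any pair was 28.8.

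Everything else was computed from these counts. Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept, 96314 cells in all and 4778 to 8432 per mouse. Doublets were predicted per library against simulated doublets (2 per cell), at an expected 0.8% per 1000 barcodes, and 5993 cells were removed. The 2000 most variable genes, scaled with a limit of 10, gave 50 principal components, and a graph of 15 neighbours was split by the Leiden method at resolution 1 into 46 clusters (65 at resolution 2). Igf1 and mitochondrial, ribosomal protein and sex-linked genes took no part in clustering. A cluster took the name of the class whose markers it showed, with at least 3 markers at 4 times the median cluster and in 10% of its cells. Names end in "like" because no protein was measured. The 3975 cells of clusters without a name stayed out, of which 1988 came from young mouse 2, 37.7% of its cells. A further clustering used 2000 variable genes that no class called between the ages (45 clusters), since 936 of the main variable genes were called.

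UMIs were summed per mouse and class, with at least 20 cells per mouse and at least 3 mice per age, which left 17 classes and left out natural killer and plasma cells. Each class was fitted with edgeR (filterByExpr, TMM factors, quasi-likelihood F test) with the mouse as the replicate and no covariate, and p was adjusted by Benjamini and Hochberg over the genes of the class, with a threshold of 0.05. CPM values beside edgeR results are TMM-normalized means over mice with the SD, and those of Igf1 are plain, without such factors. Gene lists (32) were tested in CAR-like, endothelial-like and HSC/MPP-like cells where at least 5 members passed the filter, by camera with a preset correlation of 0.01, with p adjusted over the lists of a class. Camera compares a list with the other genes. It was repeated with a correlation estimated from the data, and fry was run in its directional and mixed forms, which do not compare with other genes. Shares and differences of Igf1 between classes were tested by exact two-sided permutation of the mice (2002 splits, smallest p = 0.0005, or 126 splits and 0.00794 in the low-ribosomal set). Correlations used all 362880 pairings of the 9 middle-age mice.

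The tests, samples, markers, gene lists, the alternatives and the rule for the genes to name were chosen before the data were examined. By that rule the text names Igf1, the 10 genes with the largest change in each direction among those past the threshold with an average log2 CPM of at least 5 (3 per direction in the smaller classes), and up to 4 members of each list with a call or a called member, by smallest p. A gene that the rule names but the text and figures leave out is not reported here. Hemoglobin, immunoglobulin, T cell receptor and mitochondrial genes and 6 named sex-linked genes (Xist, Tsix, Ddx3y, Eif2s3y, Kdm5d and Uty) stay outside the 10. Other genes on the sex chromosomes do not. Alternatives were DESeq2, limma-voom, RLE factors, no filter on low counts, at least 50 cells, a stricter cell filter (1000 genes and 5% mitochondrial UMIs), doublets kept, resolution 2, each mouse left out and the replicate number as a block. The split of the libraries by ribosomal protein UMIs, fits of single clusters and the clustering without called genes were added after the data were seen.

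Total UMIs per library were 55668946 to 139277347. Each fit was tested on simulated counts with 100 genes changed 1.5-fold and 100 changed 2-fold. With edgeR, 65% and 93% were recovered in CAR-like cells (9 wrong calls among 167), 47% and 88% in endothelial-like cells (4 among 139) and 53% and 88% in HSC/MPP-like cells (10 among 151). Camera recovered the 1 changed list, made of 20 genes, in each class with 0 wrong calls. Fry recovered it too, with 1 wrong call in CAR-like and 1 in endothelial-like data. The simulated genes were drawn independently and without an effect of the library sets, so correlation between genes was not part of this check. The permutation test of shares called 6.5% of 200 simulated shares without a change. Gene positions come from GENCODE vM21 on GRCm38. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2 and igraph 0.11.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.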

Results

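The series measured the polyadenylated RNA of single bone marrow cells from 14 B6 mice, 5 young and 9 middle-age, with 1 droplet library per mouse. Blood-forming cells and cells of the marrow's supporting tissue were sorted and loaded together, so each library holds both. The labels give no age in months, no sex and no batch. Ddx3y and Eif2s3y, which lie on the Y chromosome, were at 0 CPM in all 14 libraries, and Xist was expressed. Every mouse was thus female by its RNA. The UMI totals of young mice 1 to 5 were 97190797, 55668946, 139277347, 105194012 and 81299032. Those of middle-age mice 1 to 9 were 104873235, 111002255, 122919204, 116785079, 125854952, 108121879, 94047255, 122727276 and 101678848. The median barcode held between 5822 and 12986.5 UMIs, depending on the library.

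Marker genes gave a class name to 86346 of the 90321 cells kept. The stromal class was CAR-like (16595 cells, 455 to 1646 per mouse), which carries Cxcl12, Lepr, Adipoq and Kitl, the marks of CXCL12-abundant reticular cells, the perivascular stroma that feeds blood stem cells. A smaller cluster of 2002 cells carried both CAR and bone-forming markers and is called CAR/osteolineage-like. Vessel lining gave 4235 endothelial-like cells, 140 to 506 per mouse. The largest blood class was HSC/MPP-like (20791 cells, 667 to 1955 per mouse), which joins clusters with markers of hematopoietic stem cells and of multipotent progenitors. Ribosomal protein genes took 28.8 to 29.5% of the UMIs of middle-age mice 2, 4, 6 and 8 and 26.4% of those of young mouse 3, against 21.4 to 24.0% in the other 9 libraries. The split at 25% is explained by no label and was set after the data were seen. Among middle-age mice it falls on the even replicate numbers, but young mice 2 and 4 lie under 25% and young mouse 3 above. The 9 libraries under 25%, 4 young and 5 middle-age, are called the low-ribosomal set below and give a within-set value. The other set has 1 young mouse, too few for a test of its own.

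The title of the series names a decline of IGF1 in CAR cells, and the gene, Igf1 (insulin-like growth factor 1), was compared between the ages. In CAR-like cells Igf1 averaged 628 ± 86.5 CPM (UMI counts scaled to the total of the mouse's cells of the class; SD, n = 5) in young mice and 310 ± 55.6 CPM (SD, n = 9) in middle-age mice. That is 49.4% of the young mean. The groups did not overlap, at 520 to 734 CPM against 246 to 426 CPM. The two-sided exact permutation test gave p = 0.0005, the smallest that 2002 splits of the mice allow. With edgeR the gene fell by 1.01 on the log2 scale (SE 0.11, adjusted p = 1.47e-05, lower than the young median in 9 of 9 mice). Igf1 is ENSMUSG00000020053, on chromosome 10 from 87858265 to 87937042 of GRCm38. The cells with an Igf1 UMI, each cell thinned to 2000 UMIs, fell from 65.0 ± 5.42% (SD, n = 5) to 41.8 ± 5.02% (SD, n = 9) of CAR-like cells (exact permutation p = 0.0005). Neutrophil-like cells, which should lack the gene, had 0.647 ± 0.656% and 0.258 ± 0.192% such cells (exact permutation p = 0.0994). Their median depths were 4707.5 UMIs in young and 5254 in middle-age mice. The depths were 7311.5 and 6103 in CAR-like cells. Within the low-ribosomal set the CAR-like level was 655 ± 71.6 CPM (SD, n = 4) in young and 340 ± 55.6 CPM (SD, n = 5) in middle-age mice. The exact permutation p was 0.00794, the smallest that 126 splits allow. In the other set, the young mouse had 520 CPM and the 4 middle-age mice 273 ± 27.3 CPM.

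**Figure D1:**
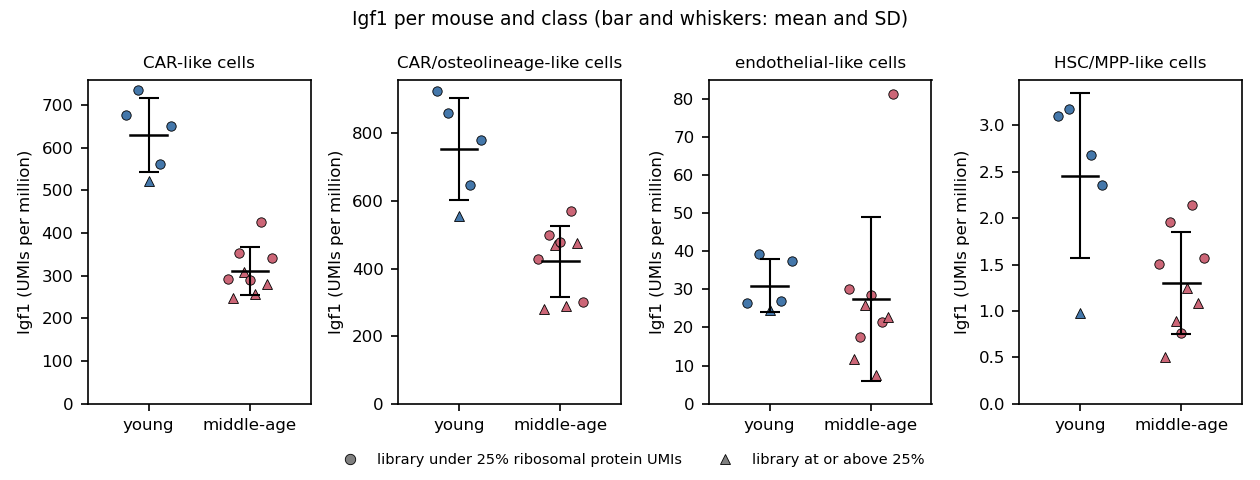
Igf1 in CPM per mouse (vertical axis) in the classes named on the panels, young and middle-age mice side by side, each point 1 library, with the mean and SD as bars. In CAR-like cells the 5 young mice lie at 520 to 734 CPM and the 9 middle-age mice at 246 to 426 CPM.

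Outside the CAR-like class, Igf1 also fell in CAR/osteolineage-like cells, from 754 ± 152 CPM (SD, n = 5) to 421 ± 105 CPM (SD, n = 9), by 0.81 on the log2 scale (SE 0.15, edgeR adjusted p = 0.00217). In osteolineage-like cells, at 45.1 ± 32.7 and 8.44 ± 10.6 CPM, Igf1 did not pass the filter on low counts. It was called there at resolution 2 (log2 -2.80, adjusted p = 2.54e-04) and without the filter (-2.18, adjusted p = 0.0205), and not with doublets kept (-1.19, adjusted p = 0.756), with stricter cells (-2.09, adjusted p = 0.9996) or within the low-ribosomal set (-2.40, adjusted p = 0.068). Of the 8 fits without 1 mouse in which it passed the filter, 7 gave no call (adjusted p = 0.186 to 0.375). Endothelial-like cells had 31.0 ± 6.90 CPM and 27.4 ± 21.5 CPM, a log2 difference of -0.04 (SE 0.33, adjusted p = 0.973). That value rests on middle-age mouse 9, at 81.2 CPM, without which the difference is -0.52 (adjusted p = 0.0791). Cluster 12 of the main clustering alone, which has sinusoidal markers, had 0.58 (adjusted p = 0.226). HSC/MPP-like cells had 2.46 ± 0.890 and 1.30 ± 0.549 CPM, a log2 difference of -0.81 (SE 0.27, adjusted p = 0.0774), and without young mouse 3 it passes the threshold at -1.01 (adjusted p = 0.0178). It also passes with DESeq2 (-0.82, adjusted p = 0.0372) and in cluster 2 alone (-1.17, adjusted p = 0.0303). Cycling progenitors had a log2 difference of -0.99 (SE 0.38, adjusted p = 0.325). A permutation of ages over mice, with 1 CPM added to each value, tested whether the decline differs between classes. The log2 difference of CAR-like cells from cycling progenitor cells was -0.54 (exact permutation adjusted p = 0.00799) and from HSC/MPP-like cells -0.44 (adjusted p = 0.016). The added CPM shrinks the change of these low classes, and edgeR's changes of -1.01, -0.99 and -0.81 lie close together, so no deeper decline in CAR-like cells is claimed. With 0.5 CPM added the values are -0.35 and -0.31 (adjusted p = 0.212 for each). Without young mouse 3 the HSC/MPP-like difference is -0.32 (adjusted p = 0.0699), and within the low-ribosomal set the values are -0.52 and -0.37 (adjusted p = 0.0635 for each). Against endothelial-like and CAR/osteolineage-like cells, differences of -0.61 and -0.17 did not pass (exact permutation adjusted p = 0.191 and 0.27).

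The next question is what else changed in CAR-like cells. Among the genes that passed were matrix genes and secreted factors. Mgp, a matrix protein that restrains mineral deposition, rose from 831 ± 166 CPM (SD, n = 5) to 3638 ± 898 CPM (SD, n = 9). Dcn and Lum, leucine-rich proteoglycans that bind collagen, rose from 312 ± 81.5 to 1007 ± 245 CPM and from 29.2 ± 18 to 107 ± 24.1 CPM. Snhg11 went from 9.98 ± 2.82 to 184 ± 27.8 CPM. Il15, a cytokine for natural killer and T cells, fell from 58.0 ± 7.42 to 30.3 ± 5.24 CPM. Angpt1, a ligand of the receptor Tie2 on stem and endothelial cells, fell from 359 ± 48.5 to 202 ± 51.4 CPM. In all, 842 of 12944 genes passed edgeR's test at an adjusted p under 0.05, 500 higher and 342 lower in middle age.

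Among the 10 genes with the largest rise in CAR-like cells at an average log2 CPM of at least 5, the log2 changes were 4.13 for Snhg11 (SE 0.16, adjusted p = 6.98e-12), 2.13 for Mgp, 2.06 for Fndc1, 1.83 for Lum, and 1.69 for Dcn. They were 1.46 for the metallothionein Mt2, 1.34 for the neutrophil chemokine Cxcl5, 1.32 for the AMP deaminase Ampd3 and 1.30 for Enpp2, which makes lysophosphatidic acid. Gm21860 completes them at 1.43 (adjusted p = 0.0463), but leaving out any of 10 of the mice ends its call (highest adjusted p = 0.136). The annotation puts it on chromosome Y, from 90754513 to 90754821. The mice are female by their RNA, so the source of its UMIs is not settled and no rise is claimed for it. At that expression Timp4, an inhibitor of matrix proteases, had the largest fall, by 1.42 (adjusted p = 1.03e-04). After it came Igfbp3 and Pcsk5, each at -1.04, Igf1, Cnnm1 at -0.96, Il15 and Slc24a3 each at -0.93, the cartilage collagen Col11a1 at -0.91, Ifitm1 at -0.86 and Angpt1 at -0.83. Gm21860 and Col11a1 did not pass within the low-ribosomal set (adjusted p = 0.342 and 0.0745). Each gene of this paragraph lay beyond the young median in 9 of 9 middle-age mice. Snhg11 is ENSMUSG00000044349, on chromosome 2 from 158375638 to 158386145, and Mgp is ENSMUSG00000030218, on chromosome 6 from 136872435 to 136875823, both in GRCm38.

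The IGF system, whose members carry, bind or free the hormone, moved in parts in CAR-like cells. Of 13 measured members 3 fell and 1 rose, and 4 fell and 2 rose when p was adjusted over the list alone. Igfbp3, a carrier of IGF1, fell by 1.04 and Pappa, a protease that frees IGF1 from its carriers, by 0.52 (adjusted p = 0.00207). The receptor gene Igf1r rose by 0.47 (adjusted p = 0.00994). As a whole the list did not pass camera (median -0.14, adjusted p = 0.0919). Of 18 niche factors, 5 fell and 1 rose (6 and 1 adjusted over the list alone), and the list was lower (median -0.09, adjusted p = 0.0437), a call that is lost with an estimated correlation (adjusted p = 0.272) and without any of 7 mice (highest adjusted p = 0.072). Besides Il15 and Angpt1, the adhesion molecule Vcam1 fell by 0.58 and Bmp4, a growth factor of the stem cell niche, by 0.59. Adipogenic genes went both ways, 2 up and 2 down of 15 (the same counts adjusted over the list alone; median 0.08, adjusted p = 0.936). Pparg, the master regulator of fat cells, fell by 0.59 and lipoprotein lipase Lpl by 0.68, while Acsl1 rose by 0.45. Of 14 osteogenic genes, 5 fell and 2 rose (6 and 2 adjusted over the list alone; median -0.13, adjusted p = 0.128, and 0.0209 in the low-ribosomal set), with Ibsp at -0.73, Sparc at -0.61, Mef2c at -0.42 and Phex, which regulates phosphate, at 1.03. Of 26 collagen and matrix genes 9 fell and 5 rose (10 and 5 adjusted over the list alone; median -0.13, adjusted p = 0.102), with Fn1 at -2.46 from 6.35 ± 1.94 CPM.

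Lists of stress, signalling, translation, respiration and MHC genes were called in CAR-like cells. None of them holds with an estimated correlation, whose adjusted p is given for each. Of 13 heat shock genes 3 fell (7 adjusted over the list alone; median -0.36, adjusted p = 0.00191, and adjusted p = 0.61 with an estimated correlation). The chaperone of the endoplasmic reticulum Hspa5 fell by 0.52, but not without young mouse 1 (adjusted p = 0.0755). Hsp90ab1 and Hsph1 lose their calls without any of 3 and of 4 mice (highest adjusted p = 0.0931 and 0.129). Of 22 targets of IGF1 and mTOR signalling, 5 rose (5 up and 1 down adjusted over the list alone), among them the cholesterol genes Insig1 at 1.08 and Sqle at 1.35 (Sqle did not pass within the low-ribosomal set). That list was higher (median 0.26, adjusted p = 0.0145, and adjusted p = 0.61 with an estimated correlation), but not without young mouse 4 (adjusted p = 0.072). Oxidative stress and metal genes, with Mt1 at 1.21, had 3 of 18 up (7 adjusted over the list alone; median 0.18, adjusted p = 0.0437, and adjusted p = 0.61 with an estimated correlation). The 65 ribosomal protein genes had no member past the threshold, alone or over all genes (edgeR), and were higher as a list (median 0.24, adjusted p = 3.01e-13, and adjusted p = 0.61 with an estimated correlation). The library sets are defined by these genes. With the set as a covariate 8 members rose (median 0.15), and within the low-ribosomal set 2 did (median 0.12, adjusted p = 7.19e-10). A list call without a called member was also made for 41 genes of oxidative phosphorylation (median 0.13, adjusted p = 0.0179, and adjusted p = 0.809 with an estimated correlation) and 16 MHC genes (median 0.20, adjusted p = 0.0254, and adjusted p = 0.719 with an estimated correlation). In the low-ribosomal set oxidative phosphorylation turns to lower (adjusted p = 0.348), and the adjusted p is 0.168 for the MHC genes, 0.0916 for the IGF1 and mTOR targets and 0.0999 for oxidative stress, so 4 of the calls end there. Leaving out 1 mouse ends the call of the MHC genes 5 times, of oxidative phosphorylation 6 times and of oxidative stress 8 times (highest adjusted p = 0.171, 0.157 and 0.114).

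Genes that mark other cells or aged stem cells were also measured in CAR-like cells. The signature of aged stem cells had 10 of 33 members up and 1 down (14 and 6 adjusted over the list alone; median 0.13, adjusted p = 0.0133, and adjusted p = 0.0894 with an estimated correlation), with Ampd3, Enpp5 at 0.56, Jam2 at 0.96 and Klhl4 at 1.75. Immunoglobulin genes, which CAR cells lack, rose in 3 of 4 measured (4 adjusted over the list alone; too few for a list test), with Igkc at 2.22 (9.74 ± 11.2 to 43.4 ± 21.2 CPM). Of the other called members, Ighm loses its call without young mouse 1 or 4 (highest adjusted p = 0.102) and Jchain without young mouse 1, 4 or 5 (highest adjusted p = 0.0763). At resolution 2 Jchain turns to -1.27 (adjusted p = 0.34). Neutrophil granule genes were higher as a list with 0 of 10 past the threshold (edgeR; 0 adjusted over the list alone; median 0.38, adjusted p = 0.0165, and adjusted p = 0.61 with an estimated correlation), but not without young mouse 1 or young mouse 4 (adjusted p up to 0.0884). Of 6 genes typical of CAR cells, Cxcl14 rose by 0.59 and Lpl fell (the same adjusted over the list alone; median -0.13, adjusted p = 0.531). The remaining lists did not pass camera in this class; after each count over all genes (edgeR) stands the count adjusted over the list alone. These were interferon response (1 up and 0 down of 30, 1 and 0, with Ifi204 at 0.44; adjusted p = 0.933, but higher in the low-ribosomal set at 0.0099), inflammatory genes (2 up and 2 down of 18, 5 and 3; adjusted p = 0.92), immediate early genes (0 up and 0 down of 19, 0 and 0; adjusted p = 0.677), glycolysis (0 up and 0 down of 14, 0 and 0; adjusted p = 0.374), hypoxia targets (2 up and 0 down of 15, 2 and 1; adjusted p = 0.531), senescence (1 up and 1 down of 10, 2 and 1; adjusted p = 0.55) and the cell cycle (1 up and 0 down of 32, 0 and 0; adjusted p = 0.221). Self-renewal genes (1 up and 0 down of 13, 2 and 1; adjusted p = 0.55), lymphoid priming (2 up and 1 down of 15, 2 and 1; median -0.04 and mean 0.08; adjusted p = 0.92), myeloid priming (0 up and 0 down of 15, 0 and 0; adjusted p = 0.163), megakaryocyte priming (0 up and 0 down of 9, 0 and 0; adjusted p = 0.221), endothelial activation (0 up and 1 down of 7, 0 and 1; adjusted p = 0.936) and hemoglobin genes (0 up and 0 down of 5, 0 and 0; median 1.41; adjusted p = 0.523) did not pass either. Of 2 macrophage, 2 platelet and 3 endothelial genes, too few for a list test, 0 passed (edgeR), with 1 endothelial gene lower adjusted over the list alone.

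The count of 842 genes in CAR-like cells drops to 550 without young mouse 1. Within the low-ribosomal set 772 genes passed, 569 of the 842 among them. The number of called lists, 9, is 3 without young mouse 4, 4 without young mouse 1, 5 without middle-age mouse 6 and 0 with an estimated correlation.

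In endothelial-like cells, 1297 of 10261 genes passed edgeR's test (767 higher and 530 lower). Among the genes that rose, Alpl went from 9.59 ± 6.21 CPM (SD, n = 5) to 58.9 ± 18.6 CPM (SD, n = 9), and Gja4, a gap junction protein of arteries, from 21.5 ± 10.4 to 114 ± 57.0 CPM. Among the genes that fell, E-selectin, Sele, which lets leukocytes stick to the vessel wall, went from 489 ± 80.4 to 172 ± 90.9 CPM, P-selectin, Selp, from 450 ± 44.6 to 221 ± 75.3 CPM, and the chemokine carrier Ackr1 from 386 ± 54.0 to 179 ± 46.1 CPM. The cells also came from a different mixture of vessels. With clusters made from genes that no class called, the cluster with sinusoidal markers held 91.0 ± 5.90% of the class in young and 72.1 ± 11.7% in middle-age mice (exact permutation p = 0.00849, and p = 0.0238 in the low-ribosomal set), and the cluster with capillary and arterial markers held the rest. Fitted alone, clusters 12, 20 and 27 of the main clustering called 118, 308 and 2 genes.

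The 10 largest rises in endothelial-like cells at an average log2 CPM of at least 5 were log2 changes of 2.84 for Alpl (SE 0.32, adjusted p = 1.28e-05), 2.77 for Slc26a10, 2.74 for Nebl, 2.51 for the carbonic anhydrase Car4, and 2.38 for Rgs5. Next were 2.36 for the collagen Col8a1, 2.34 for Stmn2, 2.29 for Gja4, 2.26 for the angiotensin-converting enzyme Ace and 2.2 for Car8. The largest falls at that expression were -1.51 for the viral receptor and junction protein Cxadr (SE 0.17, adjusted p = 1.28e-05), -1.50 for Pwwp3b, -1.48 for Sele, and -1.40 for Lalba. After them came -1.28 for the zinc carrier Slc39a8, -1.26 for Reep1, -1.23 for Ibsp, -1.21 for Clca3a1 and -1.18 for Cd55, a brake on complement. The interferon-induced chemokine Cxcl10 fell by 1.27, but not without young mouse 5 (adjusted p = 0.0672). Ibsp and Clca3a1 did not pass within the low-ribosomal set (adjusted p = 0.098 and 0.0702). Ibsp is also a leading gene of CAR-like clusters and Col8a1 of the CAR/osteolineage-like cluster. The part that leaked RNA has in their endothelial-like values was not measured. Each of these 20 genes moved in at least 8 of 9 middle-age mice. Alpl is ENSMUSG00000028766, on chromosome 4 from 137741733 to 137796384 of GRCm38.

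**Figure D2:**
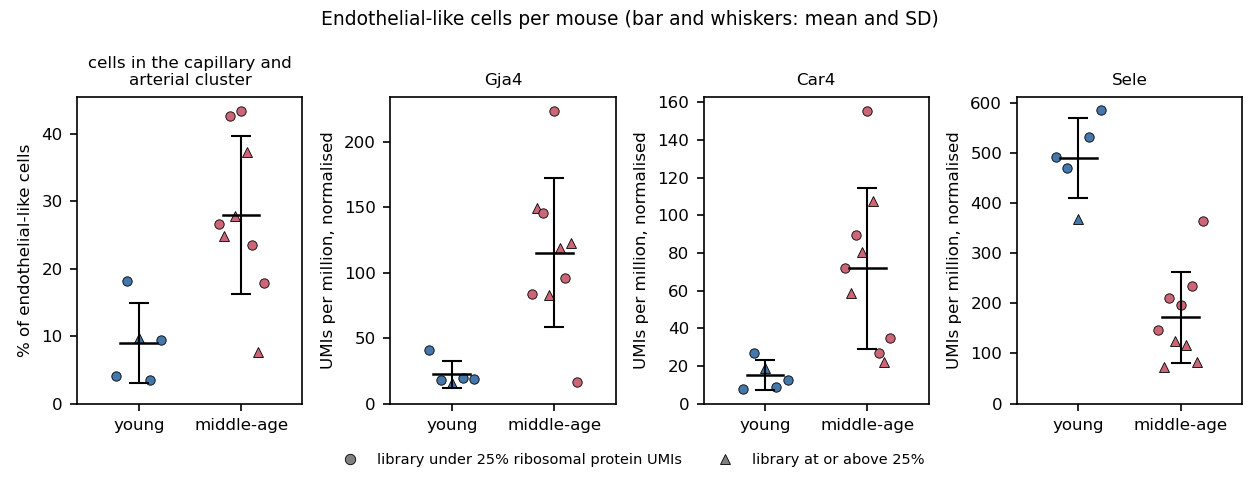
Endothelial-like cells per mouse, young and middle-age mice side by side, each point 1 library, with the mean and SD as bars: the percent of the class in the capillary and arterial cluster, then Gja4, Car4 and Sele in normalised CPM. Sele goes from 489 to 172 CPM and Gja4 from 21.5 to 114 CPM.

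Niche factors rose in endothelial-like cells, with 7 of 15 up and 1 down (8 and 1 adjusted over the list alone; median 0.56, adjusted p = 0.0153, and adjusted p = 0.157 with an estimated correlation). Cxcl12, which retains stem cells in the marrow, rose from 637 ± 167 to 1630 ± 534 CPM and the stem cell factor gene Kitl from 154 ± 50 to 411 ± 155 CPM. Cxcl12 and Kitl are also leading genes of CAR-like clusters. The parts that leaked RNA and the changed mixture of vessels have in their endothelial-like values were not measured. Bmp6, a regulator of iron, rose by 2.12. Antigen presentation rose too, with 9 of 17 MHC genes up (10 adjusted over the list alone; median 0.44, adjusted p = 2.2e-08, and adjusted p = 0.281 with an estimated correlation). The class II genes led, with H2-Ab1 at 1.80, H2-Eb1 at 1.94 and H2-Aa at 1.70. Endothelial activation was lower, with 6 of 12 down and 3 up (8 and 3 adjusted over the list alone; median -0.66, adjusted p = 0.0153, and adjusted p = 0.157 with an estimated correlation). Its members split, since Selp and Ackr1 fell by 1.02 and 1.12 while Vwf, a clotting factor stored by endothelium, rose by 2.17 and the nitric oxide synthase Nos3 by 1.03. Ackr1 is among the sinusoidal markers and Vwf among the arterial markers used to name clusters. The list's change is thus not told apart from the changed mixture of vessels. Vcam1 fell by 1.05, and in the low-ribosomal set by 0.84 (adjusted p = 0.0804). The IGF system had 2 up and 3 down of 11 (3 and 3 adjusted over the list alone; median -0.04, adjusted p = 0.303). Igfbp2 fell most, by 3.53 (SE 0.33, adjusted p = 2.14e-06), from 34.4 ± 7.0 to 3.17 ± 2.87 CPM, Igfbp4 fell by 0.57 and Igfbp3 rose by 1.23.

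Oxidative phosphorylation was higher as a list in endothelial-like cells, with 0 of 41 members past the threshold (edgeR; 0 adjusted over the list alone; median 0.21, adjusted p = 0.00128, and adjusted p = 0.601 with an estimated correlation), a call absent from the low-ribosomal set (adjusted p = 0.224). Oxidative stress genes had 3 of 15 up (4 up and 1 down adjusted over the list alone; median 0.16, adjusted p = 0.0432, and adjusted p = 0.281 with an estimated correlation), with the glutathione transferases Gstm2 at 1.76 and Gstm1 at 1.16. Senescence genes had 2 of 8 up, Bcl2l1 at 0.74 (not past the threshold within the low-ribosomal set) and Igfbp3 (5 adjusted over the list alone; median 0.70, adjusted p = 0.0432, and adjusted p = 0.193 with an estimated correlation). Leaving out 1 mouse ends these last calls 6 and 5 times (highest adjusted p = 0.0878 for each). Neutrophil granule genes, which belong to other cells, were higher (3 of 9 up, 8 adjusted over the list alone; median 1.6, adjusted p = 0.00554, and adjusted p = 0.311 with an estimated correlation). Ngp rose by 1.74 with a wide spread, from 20.5 ± 7.47 to 66.2 ± 82.4 CPM, and loses its call without young mouse 1, 3 or 4 (highest adjusted p = 0.0808).

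Flow-responsive Klf2 rose by 1.26 and Klf6 by 0.74 among 18 immediate early genes (3 up and 1 down, 5 and 2 adjusted over the list alone; median 0.11, adjusted p = 0.244, and 0.0319 in the low-ribosomal set). The chaperone genes Hspa5 and Hsph1 fell by 0.83 and 1.14 among 14 heat shock genes (2 down; 2 up and 3 down adjusted over the list alone; median -0.11, adjusted p = 0.153). Of the other lists in this class, none passed camera, and the count adjusted over the list alone again follows that over all genes (edgeR). These were collagen and matrix (5 up and 4 down of 20, 7 and 5, with Lama4 at 1.12 and Fn1 at 1.61; adjusted p = 0.98), adipogenic genes (1 up and 3 down of 14, 2 and 3, with Apoe at -0.67; adjusted p = 0.404), osteogenic genes (1 up and 1 down of 7, 1 and 2; median -0.36 and mean 0.02, with the test pointing down; adjusted p = 0.544), interferon response (3 up and 3 down of 29, 5 and 4, with Rsad2 at 1.02 and Ifi204 at -0.84; adjusted p = 0.773) and inflammatory genes (2 up and 3 down of 12, 2 and 5, with Icam1 at -0.82; adjusted p = 0.128). Glycolysis (1 up and 0 down of 12, 3 and 0; adjusted p = 0.153), hypoxia targets (3 up and 0 down of 14, 5 and 2, with Ddit4 at 1.10; adjusted p = 0.336), the cell cycle (0 up and 0 down of 20, 0 and 0; adjusted p = 0.84), ribosomal proteins (0 up and 0 down of 65, 0 and 0; adjusted p = 0.98, but lower in the low-ribosomal set at 8.6e-05 and with the set as a covariate at 0.0078, the latter lost with an estimated correlation at 0.634), aged stem cell genes (10 up and 6 down of 30, 13 and 6; adjusted p = 0.204) and self-renewal genes (5 up and 1 down of 16, 6 and 2, with Mecom at 2.0; adjusted p = 0.235) stayed under it too. So did lymphoid priming (2 up and 0 down of 9, 2 and 0, with Ebf1 at 1.35; adjusted p = 0.122), myeloid priming (0 up and 2 down of 12, 2 and 2, with the test pointing up; adjusted p = 0.404), megakaryocyte priming (2 up and 1 down of 8, 3 and 1; adjusted p = 0.153), IGF1 and mTOR targets (4 up and 0 down of 17, 5 and 0; adjusted p = 0.0872), hemoglobin genes (0 up and 1 down of 5, 4 and 1; median 1.51; adjusted p = 0.854), CAR cell genes (2 up and 1 down of 6, 2 and 1; adjusted p = 0.84) and endothelial genes (1 up and 0 down of 6, 3 and 1; adjusted p = 0.248). Of 2 immunoglobulin genes, 2 macrophage genes and 1 platelet gene, too few for a list test, 0 passed (edgeR), with 1 immunoglobulin gene higher and 1 macrophage gene each way adjusted over the list alone.

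Leaving out 1 mouse at a time gave 939 to 1879 called genes in endothelial-like cells, the highest without middle-age mouse 9. Within the low-ribosomal set 775 passed, 687 of the 1297 among them.

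In HSC/MPP-like cells, the class that would carry a shift of stem cells toward myeloid output, genes known from aged stem cells rose together. Of 40 measured members of a published signature of stem cell aging, 35 rose and 0 fell (36 and 0 adjusted over the list alone; median 1.86, adjusted p = 8.59e-43, and adjusted p = 0.0195 with an estimated correlation). With an estimated correlation and the library set as a covariate the list does not pass (adjusted p = 0.0573). Aldh1a1, a retinal dehydrogenase, went from 6.87 ± 0.890 CPM (SD, n = 5) to 49.0 ± 8.10 CPM (SD, n = 9). The phospholipid scramblase Plscr2 went from 1.56 ± 0.667 to 21.3 ± 2.57 CPM, the sulfotransferase Sult1a1 from 4.37 ± 0.623 to 36.8 ± 7.62 CPM and the transcriptional coactivator Wwtr1 from 0.380 ± 0.165 to 6.27 ± 0.70 CPM. In all, 1143 of 13993 genes passed edgeR's test, 842 higher and 301 lower.

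**Figure D3:**
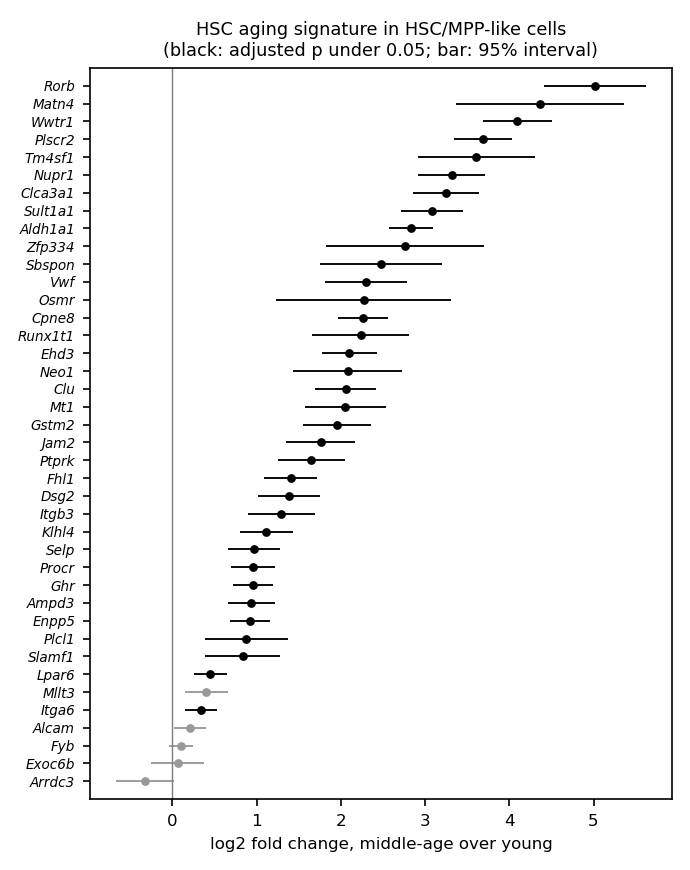
Log2 fold change between middle-age and young mice of the measured members of the stem cell aging signature in HSC/MPP-like cells, with error bars as labelled on the plot. Of 40 members 35 passed the threshold, all of them upward, with a median of 1.86.

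Lists of self-renewal and megakaryocyte genes were higher and that of lymphoid priming lower in HSC/MPP-like cells. The class joins clusters whose parts vary. With clusters made from genes that no class called, the cluster with multipotent progenitor markers held 42.0 ± 3.33% of the class in young and 31.2 ± 8.25% in middle-age mice (exact permutation p = 0.0215, adjusted p = 0.0644). A cluster with stem cell markers held 4.84 ± 6.79% and 29.6 ± 32.7% (adjusted p = 0.267), and it followed the library sets. It held 59.0 to 68.8% in middle-age mice 2, 4, 6 and 8, 16.8% in young mouse 3 and at most 4.97% in the others. The larger cluster with stem cell markers held 53.2 ± 7.72% and 39.1 ± 30.1% (adjusted p = 0.305). Within the low-ribosomal set these clusters, in the order given, differed by -7.49, 0.334 and 7.15 percentage points (exact permutation p = 0.19, 0.643 and 0.262). Camera was not run within these clusters, so mixture and a change within cells are not told apart. Self-renewal genes had 7 of 20 up and 0 down (12 and 1 adjusted over the list alone; median 0.34, adjusted p = 3.88e-06, and adjusted p = 0.189 with an estimated correlation), with Hoxb5 at 1.34, Cdkn1c, a brake on the cell cycle, at 1.0, Procr at 0.96 and Pdzk1ip1 at 0.80. Megakaryocyte priming had 7 of 15 up (9 adjusted over the list alone; median 0.47, adjusted p = 2.06e-06, and adjusted p = 0.0653 with an estimated correlation), with Vwf at 2.30, the fibrinogen receptor chain Itgb3 at 1.29 and Selp at 0.97. Vwf, Itgb3 and Selp are also members of the aging signature, as is Procr of the self-renewal list. These lists are therefore not independent of the signature, and they were not tested without the shared members. Lymphoid priming had 4 of 18 down and 0 up (4 and 0 adjusted over the list alone; median -0.18, adjusted p = 0.0114, and adjusted p = 0.189 with an estimated correlation). Flt3, a receptor of lymphoid-primed progenitors, fell by 0.48 from 111 ± 14.1 to 79.3 ± 10.5 CPM, and the chromatin organizer Satb1 by 0.44. Ikzf1, needed for lymphoid commitment, fell by 0.33, but not without young mouse 1, 2 or 4 (highest adjusted p = 0.0612) nor within the low-ribosomal set (adjusted p = 0.143). Myeloid priming did not move as a list (1 of 20 down, the same adjusted over the list alone; median -0.10, adjusted p = 0.783). Cell cycle genes were lower (2 of 34 down, 7 adjusted over the list alone; median -0.29, adjusted p = 2.74e-06, and adjusted p = 0.484 with an estimated correlation). Its called members, the helicase subunits Mcm4 and Mcm6 at -0.53 and -0.36, lose their calls without any of 12 and of 7 mice (highest adjusted p = 0.114 and 0.108).

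The lists of MHC genes and of oxidative stress and metal genes were also higher in HSC/MPP-like cells, calls that end with an estimated correlation. MHC genes had 7 of 17 up (11 adjusted over the list alone; median 0.36, adjusted p = 4.54e-10, and adjusted p = 0.189 with an estimated correlation), with the class II genes H2-Eb1, from 12.4 ± 5.37 to 46.3 ± 11.7 CPM, and H2-Aa, and their chaperone Cd74 at 1.43. Oxidative stress genes had 7 of 19 up and 1 down (the same adjusted over the list alone; median 0.16, adjusted p = 0.00416, and adjusted p = 0.38 with an estimated correlation), with the metallothioneins Mt1 at 2.05 and Mt2 at 3.53 and the heme oxygenase Hmox1 at -0.99. Mt1 is also a member of the aging signature, so this list is not independent of it. Ribosomal proteins were higher as a list (0 of 65 past the threshold with edgeR, 0 adjusted over the list alone; median 0.28, adjusted p = 7.3e-10, and adjusted p = 0.62 with an estimated correlation). Oxidative phosphorylation (0 of 41, 0 adjusted over the list alone; median 0.14, adjusted p = 0.0286, and adjusted p = 0.835 with an estimated correlation) was not higher within the low-ribosomal set (adjusted p = 0.578), and 9 of the omissions of 1 mouse end its call (highest adjusted p = 0.223). Endothelial activation was higher (3 up and 2 down of 8, 4 and 2 adjusted over the list alone; median 0.26, adjusted p = 0.0497, and adjusted p = 0.189 with an estimated correlation), which 10 such omissions end (highest adjusted p = 0.0975). The IGF system had 2 of 12 up (3 up and 2 down adjusted over the list alone; median 0.08, adjusted p = 0.196), with the growth hormone receptor Ghr at 0.95. Ghr, and Selp and Vwf of the endothelial activation list, are also in the aging signature. IGF1 and mTOR targets had 1 of 22 up (1 adjusted over the list alone; median -0.02, adjusted p = 0.798).

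The largest rises in HSC/MPP-like cells at an average log2 CPM of at least 5 were Aldh1a1 at 2.83 (SE 0.13, adjusted p = 4.42e-10), Mt1, H2-Eb1 at 1.91, H2-Aa at 1.59 and Cd74. They also hold Selenom at 1.34, Trim47 at 1.32, the platelet protein Mmrn1 at 1.26, Cenpv at 1.08 and Gng11 at 1.02. Falls were smaller. AI504432 fell by 0.52 (adjusted p = 0.00826) and Arhgap15 by 0.51. The DNA replication gene Dtl fell by 0.50, but did not pass within the low-ribosomal set. Others lose their calls when 1 mouse is left out. Cd69, a marker of recent activation, fell by 0.96 but not without young mouse 3 (adjusted p = 0.0631), and Vav3 by 0.52 but not without young mouse 1, 4 or 5 (highest adjusted p = 0.0738). Lgals1 and Fkbp5, at -0.62 and -0.60, each lose it without 4 mice (highest adjusted p = 0.0697 and 0.0874). Lgals1 did not pass within the low-ribosomal set either (adjusted p = 0.0638). Ide, the insulin-degrading enzyme, fell by 0.67, but not without young mouse 4 or 5 (highest adjusted p = 0.068) nor within the low-ribosomal set, where it was -0.41 (adjusted p = 0.226). Each of these genes moved in at least 8 of 9 middle-age mice. Aldh1a1 is ENSMUSG00000053279, on chromosome 19 from 20492715 to 20643465 of GRCm38.

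**Figure D4:**
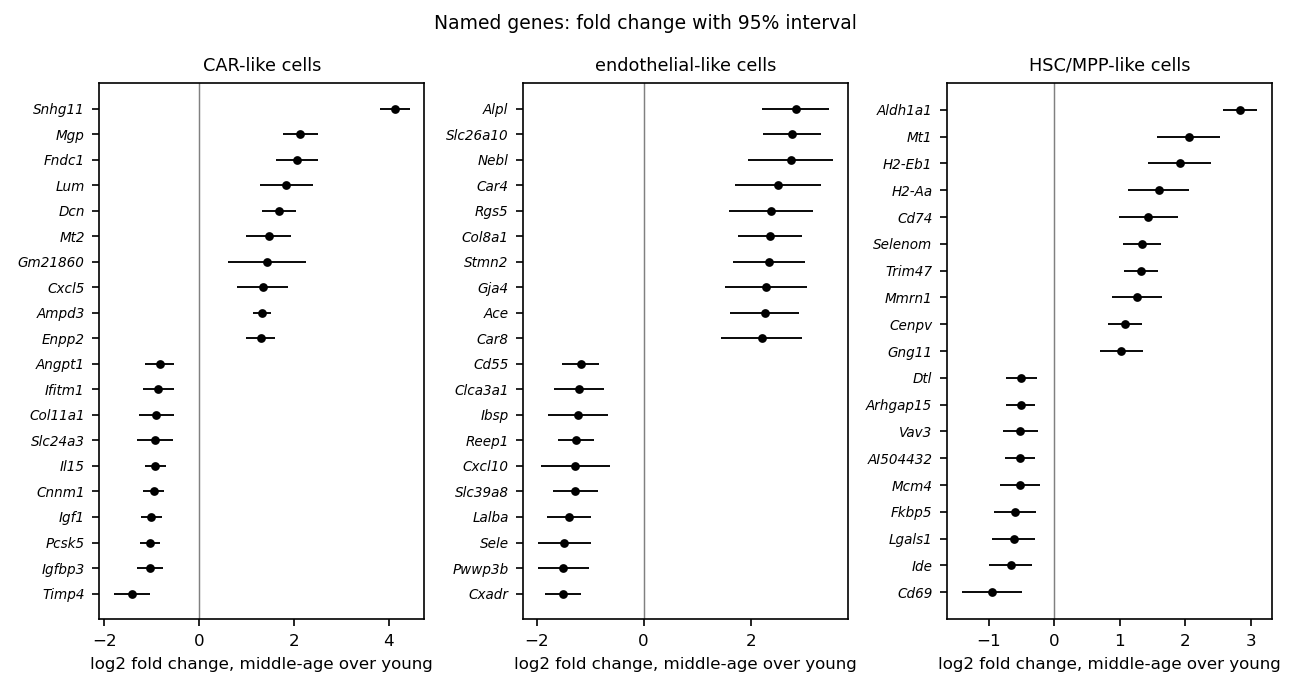
Log2 fold change between middle-age and young mice (horizontal axis, bars: 95% interval) of the genes with the largest changes at higher expression in CAR-like, endothelial-like and HSC/MPP-like cells. Values run from -1.51 for Cxadr in endothelial-like cells to 4.13 for Snhg11 in CAR-like cells.

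Genes of other cell types were followed in HSC/MPP-like cells as well. Macrophage genes were lower, 5 of 7 down (5 adjusted over the list alone; median -1.23, adjusted p = 3.31e-04, and adjusted p = 0.0722 with an estimated correlation), with the complement genes C1qa at -1.37 and C1qb at -1.23, both under 4 CPM. Neutrophil granule genes were higher (0 of 10 past the threshold with edgeR, 0 adjusted over the list alone; median 0.48, adjusted p = 0.00878, and adjusted p = 0.564 with an estimated correlation), but not without young mouse 1 (adjusted p = 0.096). Endothelial genes had 3 of 6 up (3 up and 1 down adjusted over the list alone; adjusted p = 0.0753), with Cldn5 at 2.69 from 0.598 ± 0.389 CPM. Of 4 immunoglobulin genes 1 rose (2 adjusted over the list alone) and of 1 measured T cell gene, Cd4, 1 fell (1 adjusted over the list alone), each too few for a list test, as were 4 platelet genes, of which 0 passed (edgeR; 1 adjusted over the list alone). The following lists did not pass camera, with the count adjusted over the list alone after that over all genes (edgeR). These were CAR cell genes (1 up and 0 down of 6, 1 and 0; median -0.06 and mean 0.06; adjusted p = 0.783), hemoglobin genes (0 up and 0 down of 5, 1 and 0; adjusted p = 0.456), niche factors (2 up and 2 down of 18, 3 and 2, with Bmp4 at 1.88; adjusted p = 0.44), adipogenic genes (1 up and 0 down of 12, 1 and 0; median -0.07 and mean 0.02; adjusted p = 0.918), osteogenic genes (0 up and 1 down of 10, 0 and 2; adjusted p = 0.109) and collagen and matrix (5 up and 1 down of 23, 5 and 2, with Mmp14 at 1.57; adjusted p = 0.35). The same is true of interferon response (2 up and 2 down of 30, 2 and 8; adjusted p = 0.35), inflammatory genes (0 up and 3 down of 17, 2 and 4; median 0.06 and mean -0.23; adjusted p = 0.798), immediate early genes (0 up and 0 down of 19, 0 and 0; median -0.06, with the test pointing up; adjusted p = 0.918, and 0.0134 without young mouse 3) and heat shock (1 up and 0 down of 13, 1 and 0; adjusted p = 0.43). Glycolysis (1 up and 0 down of 16, 0 and 0; adjusted p = 0.385), hypoxia targets (3 up and 1 down of 15, 3 and 3, with Ndrg1 at 0.49; median -0.08, with the test pointing up; adjusted p = 0.918) and senescence (1 up and 1 down of 9, 1 and 1, with Cdkn2c at 1.05; adjusted p = 0.774) did not pass.

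The count of 1143 genes in HSC/MPP-like cells falls to 730 without young mouse 1 and rises to 1800 without middle-age mouse 5. It is 2153 with the library set as a covariate (1168 up and 985 down, the 1143 among them) and 890 within the low-ribosomal set, of which 730 are among the 1143. Fitted alone, cluster 2 called 617 genes, with 34 genes of the aging signature up, and clusters 1 and 3 called 131, with 9 of 36 up.

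In the main fit the smaller classes had fewer called genes, and several shared a change with the large ones. CAR/osteolineage-like cells had 354 genes past edgeR's threshold (211 up and 143 down). Snhg11 rose there by 3.65 (adjusted p = 2.28e-14), while the matrix genes Fn1, Col11a1 and Lum fell by 2.13, 2.0 and 1.63, so that Lum went down here and up in CAR-like cells (the difference was not tested). Csprs at 3.11, of a multicopy family, and the microfibril gene Mfap5 at 2.50 rose with it. That count is 211 without young mouse 4 and 211 without young mouse 5. Cycling progenitors had 112 genes (81 up and 31 down), with Cenpv at 1.2 and H2-Ab1 at 0.96, and the count is 181 without middle-age mouse 5, 64 without young mouse 4 and 63 without young mouse 5. Megakaryocyte progenitor-like cells had 87 (82 up and 5 down), with Aldh1a1 at 1.77 (26.5 ± 2.73 to 90.3 ± 7.71 CPM), Mt1 at 1.47 and Clca3a1 at 1.43. Without young mouse 1, 2, 4 or 5 the count is 50, 55, 47 or 45.

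T cell-like cells, from 5 young and 8 middle-age mice, had 45 genes up and 13 down. Gzmk, a granzyme of memory T cells, rose from 4.13 ± 3.89 CPM (SD, n = 5) to 96.4 ± 54.5 CPM (SD, n = 8), and the costimulatory receptor Tnfrsf4 from 24.3 ± 14.9 to 173 ± 96.3 CPM. Cd8b1 fell from 646 ± 165 to 202 ± 119 CPM and Lef1, a transcription factor of naive T cells, from 316 ± 82.3 to 134 ± 21.1 CPM. The survival gene Bcl2a1b rose by 2.17. The 58 genes become 35 without middle-age mouse 4, 37 without middle-age mouse 8, and 25, 38 or 21 without young mouse 1, 3 or 4, and 12 within the low-ribosomal set. In lymphoid-primed progenitor-like cells 25 genes passed, and Hmga2, a growth gene of young stem cells, fell by 1.56 (SE 0.14, adjusted p = 1.45e-06), from 62.1 ± 11.2 to 21.0 ± 4.6 CPM, with Egr1 at -1.16, Cenpv at 1.79 and H2-Ab1 at 1.23. That count is 13 without young mouse 4. Myeloid progenitor-like cells had 16 genes, with Cenpv at 1.22 and the B cell factor Tnfsf13 at 1.04, and the count is 10, 9, 10 or 10 without young mouse 1, 3, 4 or 5.

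Dendritic-like cells, from 4 young and 5 middle-age mice with at least 20 cells, had 131 genes, and the replication histones Hist1h3b and Hist1h1a fell by 2.65 and 1.68. The count hangs on single mice, at 5, 6, 6 and 11 without middle-age mouse 2, 4, 6 or 8, 1277 without middle-age mouse 9, and 11, 272, 10 and 14 without young mouse 2, 3, 4 or 5. With doublets kept it is 0 (edgeR). Erythroid-like cells had 5 genes, Aldh1a1 at 1.08 among them (3 without middle-age mouse 2 and 8 without middle-age mouse 7). Osteolineage-like cells also had 5, with S100b at 1.28 and Col3a1 at -3.99 (3 to 44 when 1 mouse is left out). Basophil/eosinophil-like cells had 2, of which Fcer1a, the IgE receptor chain, rose from 147 ± 19.1 to 552 ± 149 CPM (1 to 5 when 1 mouse is left out). Neutrophil-like cells had 2 as well, with Olfm4, a granule protein, at 0.87 (adjusted p = 0.0402), a call that 8 omissions end (highest adjusted p = 0.0968), and 0 to 10 genes pass when 1 mouse is left out. B-lineage-like, monocyte-like and plasmacytoid dendritic-like cells had 0 genes with edgeR, with 588, 1033 and 273 at an unadjusted p under 0.05, and 2, 2 and 0 with DESeq2 and 0 with limma-voom.

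The title also names a myeloid bias of blood formation, which the shares of cell classes address as far as sorting allows, since the sort sets part of them. In the main clustering, B-lineage-like and lymphoid-primed cells were a smaller part of the blood cells in middle-age mice, and neutrophil-like and megakaryocyte progenitor-like cells a larger part. T cell-like cells, at 1.05 ± 0.147% and 0.865 ± 0.262%, did not pass (adjusted p = 0.267). Among named blood cells, B-lineage-like cells fell from 6.77 ± 2.03% (SD, n = 5) to 4.31 ± 1.06% (SD, n = 9), lymphoid-primed progenitor-like cells from 5.32 ± 1.21% to 3.62 ± 0.784%. Neutrophil-like cells rose from 10.1 ± 1.88% to 12.7 ± 1.04% and megakaryocyte progenitor-like cells from 5.03 ± 0.507% to 6.02 ± 0.489%. The exact permutation test gave an adjusted p of 0.0318 for each of the 4 over 15 classes, and 9 of 9 middle-age mice were on the same side of the young median. Among stem and progenitor cells alone, lymphoid-primed cells fell from 7.93 ± 1.24% to 5.36 ± 1.17% (adjusted p = 0.0175) and megakaryocyte progenitor-like cells rose from 7.58 ± 0.758% to 8.91 ± 0.815% (adjusted p = 0.0312). Myeloid progenitor-like cells, at 17.6 ± 4.62% and 19 ± 2.48% of progenitors (adjusted p = 0.469), and HSC/MPP-like cells, at 47.7 ± 3.17% and 49.8 ± 3.48% (adjusted p = 0.343), did not pass. Nor did cycling progenitors, at 19.2 ± 2.29% and 16.9 ± 2.51% (adjusted p = 0.204), but without middle-age mouse 5 they do (adjusted p = 0.0175).

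**Figure D5:**
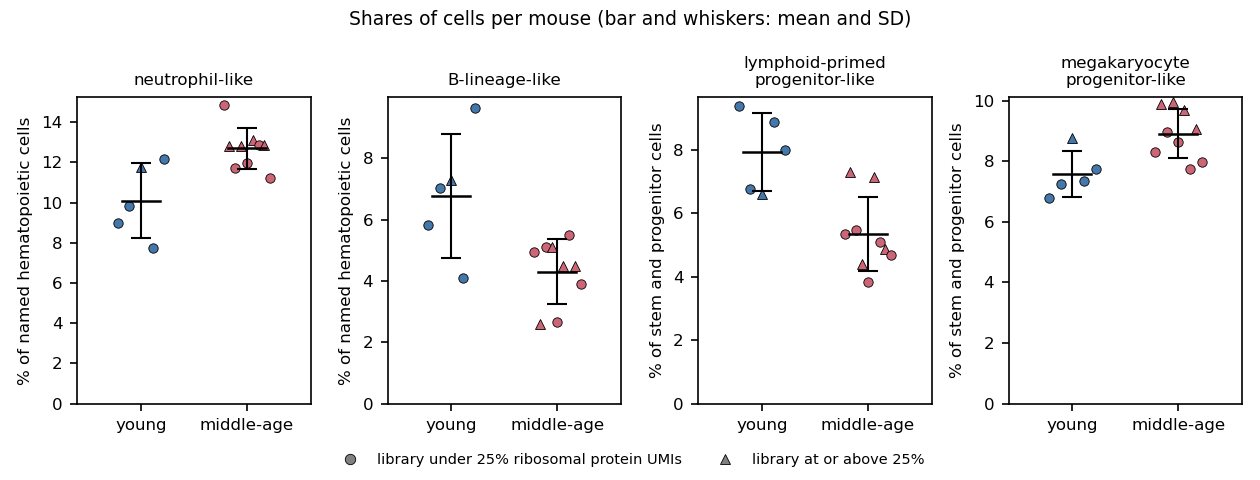
Percent of cells per mouse (vertical axis) in the cell classes named on the panels, each point 1 library, with the mean and SD per age group as bars. B-lineage-like cells go from 6.77% to 4.31% and neutrophil-like cells from 10.1% to 12.7% of named blood cells.

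Within the low-ribosomal set the exact permutation p was 0.00794 for lymphoid-primed cells among progenitors (adjusted p = 0.0397) and 0.0238 for megakaryocyte progenitor-like cells among progenitors (adjusted p = 0.0595). It was 0.0952 and 0.0556 for B-lineage-like and neutrophil-like cells among blood cells. The 4 calls among blood cells end in 8 of the 14 omissions of 1 mouse for B-lineage-like, lymphoid-primed and neutrophil-like cells and in 6 for megakaryocyte progenitor-like cells (highest adjusted p = 0.142, 0.0944, 0.0713 and 0.0769). Among progenitors, the call of lymphoid-primed cells survives every omission (highest adjusted p = 0.049) and that of megakaryocyte progenitor-like cells ends in 8 (highest adjusted p = 0.101). With clusters made from genes that no class called, where 77.9% of lymphoid-primed and 64.2% of megakaryocyte progenitor-like cells keep their name, neither share among progenitors passes (adjusted p = 0.406 for each). In those clusters, within the low-ribosomal set, the lymphoid-primed share among progenitors differs by -3.17 percentage points (exact permutation p = 0.00794), against -1.37 over all mice. The 4 calls among blood cells end there as well, with adjusted p = 0.0629 (B-lineage-like), 0.0559 (neutrophil-like), 0.46 (lymphoid-primed) and 0.213 (megakaryocyte progenitor-like).

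Among supporting cells, the planned clustering of all variable genes gave no call. CAR-like cells were 64.2 ± 4.54% (SD, n = 5) and 73.1 ± 6.05% (SD, n = 9; exact permutation adjusted p = 0.0599) and endothelial-like cells 21.8 ± 3.38% and 16.1 ± 5.36% (adjusted p = 0.0929). The CAR-like share passes without middle-age mouse 1 (adjusted p = 0.0218) or 5 (adjusted p = 0.0497). Since leading genes of these classes changed with age, the shares were also taken from the clusters made without called genes, a choice made after the data were seen. There CAR-like cells, with the CAR/osteolineage-like cells inside them, made up 74.6 ± 2.25% (SD, n = 5) of supporting cells in young and 81.6 ± 4.84% (SD, n = 9) in middle-age mice, and endothelial-like cells 22.7 ± 2.27% and 16.1 ± 5.38% (exact permutation adjusted p = 0.0345 for each, 9 of 9 mice; within the low-ribosomal set p = 0.0476 and 0.0397). Osteolineage-like cells, at 2.64 ± 0.680% and 2.25 ± 1.11%, did not pass (adjusted p = 0.488).

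The last comparison set Igf1 in CAR-like cells against progenitor shares across the 9 middle-age mice. Over 5 classes, the share of megakaryocyte progenitor-like cells gave Pearson's r = -0.70 (permutation p = 0.0313, adjusted p = 0.156) and Spearman's rho = -0.617 (permutation p = 0.0857). Without middle-age mice 3 and 7, which lie farthest from the median, r is -0.64 (permutation p = 0.123), and with finer clusters it is -0.02. For HSC/MPP-like, cycling, lymphoid-primed and myeloid progenitor-like cells r was 0.35, 0.04, -0.42 and -0.10 (permutation p = 0.367, 0.924, 0.258 and 0.777), so no relation passed the correction. Without the same 2 mice these are 0.17, 0.05, -0.75 and 0.27 (permutation p = 0.719, 0.855, 0.0476 and 0.557, adjusted p of at least 0.238). These r do not account for the library sets, between which Igf1 differs in the middle-age mice (340 CPM in 5 and 273 CPM in 4 mice). A relation apart from the sets is not tested here. No r was computed within the sets or in the 5 young mice, since each group holds fewer than 6.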

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

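The tests of the library sets and of the endothelial mixture were chosen after the result was seen, and the others were set before. The genes of the copy-number test were nevertheless chosen after their values were seen. A single mouse was set apart where its gap to the nearest other mouse was large against the range of its group, a rule that flags about 1 in 20 groups by chance, and 17 of 182 groups met it.

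The decline of Igf1 in CAR-like cells differed by permutation from that in cycling progenitors (log2 difference -0.54) and HSC/MPP-like cells (-0.44) with 1 CPM added, and not with 0.5 CPM added (-0.35 and -0.31), so it depends on the added constant. RNA that leaks from CAR-like cells into other droplets could carry the few Igf1 UMIs of HSC/MPP-like cells and their decline with them. Their Igf1 UMIs were 3.02 times (1.61 to 3.85 over mice) those that their UMIs of other CAR genes predict. That lies between the bounds of 2 and 4 set for the test. The same ratio was 0.0749 in neutrophil-like, 0.106 in myeloid progenitor-like, 1.38 in erythroid-like, 1.85 in endothelial-like and 2.06 in CAR/osteolineage-like cells. It varies widely between classes, so the bounds cannot decide. Mean Igf1 was also lower in middle age in B-lineage-like (11 to 4.24 CPM) and neutrophil-like cells (2.96 to 0.705 CPM), though not in plasmacytoid dendritic-like cells. Leaked RNA and transcription in the HSC/MPP-like cells, or CAR-like cells among them, cannot be told apart. A difference by age in the cells themselves stays open and untested.

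Ide in HSC/MPP-like cells had a mouse far from its group at each age, middle-age mouse 5 at a log2 CPM of 6.84 (others 5.62 to 6.15) and young mouse 1 at 6.27 (others 6.74 to 6.93). Its neighbours on chromosome 19, Btaf1 and Fgfbp3, chosen after their values were seen, follow it over mice, with a median r of 0.753 within age groups and library sets, so a difference in copy number of the segment between mice could be the source. The 22 other expressed genes nearby had a median r of -0.06, so both bounds of the rule set before were met. Against it, March5 between them, which that rule did not name, does not follow (r = -0.08). Hells and Slc35g1 outside the segment, the highest of the 22, do (r = 0.80 and 0.67). Among all genes compared, 187 of 11594 exceed the median of 0.753, so a difference in copy number stays open. The deviations within sets leave out a step between the sets. Over all cells Btaf1 was at 24.4 to 31.8 CPM in middle-age mice 2, 4, 6 and 8. It was at 53.0 to 62.3 CPM in the others of that age. Ide was at 40.4 to 51.1 and 62.3 to 106 CPM, while Fgfbp3 overlapped (6.63 to 7.56 and 7.06 to 8.95 CPM). Young mouse 3, also high in ribosomal protein UMIs, had 59.2 CPM of Btaf1 and 89.7 CPM of Ide. The test did not cover this step. Within the low-ribosomal set the log2 difference of Ide over all cells was -0.38 (exact permutation p = 0.0794), so the library sets cannot be told apart from age either.

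The genes called in endothelial-like cells could come from a different mixture of sinusoidal and arterial cells. Within cluster 12 of the main clustering, which has sinusoidal markers, 890 of these 1297 genes could be fitted. Their log2 differences there had a slope of 0.503 on those of the class (SE 0.0275 over genes, not mice), between the bounds set. That cluster is smaller than the sinusoidal cluster made without called genes (2157 and 3406 cells). Called genes took part in forming it, so mixture and a change within cells cannot be told apart. The slope within the low-ribosomal set was 0.964, but the genes were called over mice that include this set, which draws the slope toward that of the class. For the genes that also passed within this set, counted above, the library sets are argued against. An effect of age within vessels stays open. Middle-age mouse 9 stood apart in this class with 81.2 CPM of Igf1 (others 7.42 to 30.2) and log2 CPM values of 4.04 for Gja4 (others 6.37 to 7.80), 8.08 for Cd55 (others 6.78 to 7.44) and 4.52 for Slc26a10 (others 5.84 to 6.59).

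The other mice set apart are given as values. Gja4 in endothelial-like cells was at a log2 CPM of 5.36 in young mouse 1 (others 3.97 to 4.27) and Clca3a1 at 8.26 in young mouse 2 (others 8.64 to 8.78). In HSC/MPP-like cells, Cd69 was at 6.75 (others 5.39 to 5.52) and Cenpv at 5.14 (others 4.73 to 4.78) in young mouse 3, and Dtl at 6.77 in young mouse 4 (others 7.05 to 7.09). Cycling progenitors were 16.5% of blood cells (others 9.93 to 12.3%) and 23.2% of progenitors (others 14.9 to 18.1%) in middle-age mouse 5. Young mouse 2 had 15.4% myeloid progenitor-like cells among blood cells (others 9.98 to 11.5%), 18.2% osteolineage-like cells among supporting cells (others 1.57 to 2.60%) and 37.7% cells without a name (others 0.509 to 1.80%). CAR/osteolineage-like cells were 16.3% of supporting cells in middle-age mouse 1 (others 5.39 to 9.79%).

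Other splits of the 14 mice into 5 and 9 were fitted for comparison, the real split counted among them. As many genes were called in 2 of 100 splits in CAR-like cells (842 in the real split, 2369 in the highest other), in 1 of 100 in endothelial-like cells (1297 and 190) and in 2 of 100 in HSC/MPP-like cells (1143 and 2275). In CAR-like and HSC/MPP-like cells the highest other split drawn set middle-age mice 2, 6 and 8 and young mice 2 and 3 apart, 4 of which are libraries with more ribosomal protein UMIs. The split by library set itself, which was not drawn, calls 4824 genes in CAR-like, 7024 in HSC/MPP-like and 1068 in endothelial-like cells, more than age does in the former pair. Within the low-ribosomal set the counts were 1 of 100 in CAR-like cells (772 and 164), 2 of 100 in endothelial-like cells (775 and 1106) and 2 of 100 in HSC/MPP-like cells (890 and 2183). The number of called lists was reached by 12 of 100 splits in CAR-like cells (9 and 13), 12 of 100 in endothelial-like cells (7 and 11) and 22 of 100 in HSC/MPP-like cells (12 and 16), so chance is not excluded for it. Of 25 splits per smaller class, 1 reached the real count in CAR/osteolineage-like (354, highest other 14), cycling (112 and 7), dendritic-like (131 and 2), erythroid-like (5 and 0), lymphoid-primed (25 and 7), megakaryocyte progenitor-like (87 and 8), myeloid progenitor-like (16 and 4), osteolineage-like (5 and 4) and T cell-like cells (58 and 2). In neutrophil-like cells 2 did (2 and 15) and in basophil/eosinophil-like cells 3 (2 and 3). With 0 calls in B-lineage-like, monocyte-like and plasmacytoid dendritic-like cells (edgeR), 25 of 25 did (highest others 1, 2 and 5).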

How the results depend on the processing

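The fits of single clusters, of the library sets and of clusters without called genes were chosen after seeing the data, and the cause of the changes below was not tested. Igf1 in CAR-like cells kept its call throughout (log2 -1.07 to -0.95 with 1 mouse left out). Of the genes named over all classes, 246 of 253 kept their call with DESeq2, 254 of 255 with RLE factors, 238 of 255 with limma-voom, 233 of 253 with stricter cells, 243 of 255 with the library set as a covariate, 191 of 248 in the low-ribosomal set and 204 to 247 with 1 mouse left out. Jchain in CAR-like cells turned to -1.27 at resolution 2 and Car2 in endothelial-like cells to 0.14 with doublets kept. Leaving out 1 mouse gave 550 to 897 genes in CAR-like, 939 to 1879 in endothelial-like and 730 to 1800 in HSC/MPP-like cells, 412 to 1876 over the other classes (11 to 14 of which could be fitted, so these sums are not of the same classes), and 3 to 10, 5 to 9 and 9 to 12 lists.

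The replicate numbers do not pair the mice (correlations of same-numbered mice -0.39 to 0.21, and most mice do not correlate best with their own number). With the number as a block, which drops 4 mice, the counts were 462 in CAR-like, 398 in HSC/MPP-like and 338 in the other classes (12 fitted, against 14 in the main fit), and 186 of 246 named genes kept their call. The blocked share differences, whose smallest p is 0.0625, were -2.69 (B-lineage-like), -1.79 (lymphoid-primed), 1.10 (megakaryocyte progenitor-like) and 2.74 (neutrophil-like) percentage points of blood cells and -2.66 and 1.57 for lymphoid-primed and megakaryocyte progenitor-like cells among progenitors. Blocked Igf1 differences against cycling and HSC/MPP-like cells were -0.58 and -0.37.

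Alone, clusters 12, 20 and 27 of the endothelial-like class called 118, 308 and 2 genes, and in HSC/MPP-like cells cluster 2 called 617 and clusters 1 and 3 called 131. The low-ribosomal set called 775 in endothelial-like cells, and the covariate 2153 in HSC/MPP-like cells. The other 14 classes, 797 genes in all, had 1246 with DESeq2, 1564 without the filter and 488 with stricter cells. Over 13 classes they had 327 at resolution 2, where no cluster is CAR/osteolineage-like (354 of the 797), and 529 in the low-ribosomal set. An estimated correlation left 0, 0 and 1 lists in CAR-like, endothelial-like and HSC/MPP-like cells (0, 0 and 0 with the covariate), and fry gave 3 in CAR-like and 15 in endothelial-like cells. Lists turned direction in the low-ribosomal set for interferon response (adjusted p = 0.0099) and oxidative phosphorylation (0.348) in CAR-like cells, oxidative phosphorylation in HSC/MPP-like cells (0.578) and ribosomal proteins in endothelial-like cells (8.6e-05, and 0.0078 with the covariate).

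Share differences at resolution 2, without called genes, of all cells, with the covariate and in the low-ribosomal set were -2.52, -2.37, -1.32, -2.46 and -2.23 (B-lineage-like), -1.53, -0.905, -0.851, -1.71 and -2.24 (lymphoid-primed), 0.617, 0.463, 1.03, 0.838 and 0.848 (megakaryocyte progenitor-like) and 1.76, 2.68, 2.48, 2.40 and 2.86 (neutrophil-like). Among progenitors lymphoid-primed cells had -1.37 without called genes and -0.851 of all cells, myeloid progenitors 1.87 of all cells, and megakaryocyte progenitors 1.6 with stricter cells, 0.602 without called genes and 1.05 in the low-ribosomal set. CAR-like cells had 7.39 at resolution 2 and 6.98 without called genes, and endothelial-like cells -6.57 and -6.59. With 1 mouse left out the ranges were -3.13 to -1.75, -2.0 to -1.37, 0.838 to 1.13 and 2.01 to 3.12 for the 4 blood classes, 0.0838 to 0.119 for plasma cells, -2.90 to -2.21, 1.13 to 1.63 and -3.07 to -1.50 for lymphoid-primed, megakaryocyte and cycling cells among progenitors, and 6.91 to 9.94 for CAR-like cells. Igf1 against cycling and HSC/MPP-like cells was -0.35 and -0.31 with 0.5 CPM added and -0.52 and -0.37 in the low-ribosomal set, and -0.52 to -0.32 against HSC/MPP-like cells with 1 mouse left out. Depth and the spread between mice leave small changes unseen, since 65%, 47% and 53% of 1.5-fold changes were recovered in simulated CAR-like, endothelial-like and HSC/MPP-like data.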

Other observations

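No test in this part was planned before the data were seen, and its genes were chosen after their values were seen. Of 9556 genes tested in CAR-like, endothelial-like and HSC/MPP-like cells, 24 were called in 1 direction in all 3, 19 up and 5 down, where lists drawn independently would share 0.748. The mice are the same in the 3 classes, so chance deviations of a mouse are shared. The log2 differences in the 3 classes were 1.32, 1.34 and 0.94 for Ampd3, 0.89, 2.07 and 0.97 for the calcium-binding S100a6 and 0.96, 1.46 and 1.76 for the junction protein Jam2. They were -0.40, -0.73 and -0.40 for Dock8, a regulator of leukocyte migration. Mgp and Vcam1 are also among the 24, but in HSC/MPP-like cells they lie at 1.14 to 4.54 and 4.93 to 2.33 CPM (means of young and middle-age mice), against 831 to 3638 and 2153 to 1437 CPM in CAR-like cells. Ampd3 and Jam2 are low in HSC/MPP-like cells as well, at 3.01 to 5.74 and 2.97 to 9.79 CPM. Other genes of the 24 are low there too, such as Stab2 (0.868 to 0.377), Csprs (0.0822 to 0.570) and Cxcl14 (2.46 to 4.41 CPM). Stab2, a sinusoidal marker, has 2.15 to 0.751 CPM in CAR-like and 1829 to 957 CPM in endothelial-like cells. Dock8 is higher in HSC/MPP-like cells, at 118 to 89.6 CPM. The part that leaked RNA has in these values was not measured. No change within HSC/MPP-like cells is claimed for these low genes, nor within CAR-like cells for Stab2. The count of 24 may hold leaked RNA.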
